A study of Mus musculus with 9 samples.

How the data were processed

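Total RNA from thioglycollate-elicited peritoneal macrophages of wild-type, MyD88-deficient (MyD88 KO) and TRIF-deficient (TRIF KO) mice was labelled with biotin and hybridised to Affymetrix arrays of 22690 probe sets. There were 9 arrays, 1 for each of 3 genotypes at 0, 1 and 4 h of 100 ng/ml lipopolysaccharide (LPS). The authors deposited log2 expression values, 1 per probe set and array, which were made with RMA per the submitters' processing notes. RMA corrects the background, normalizes the quantiles of the arrays and summarises the probes of a probe set on the log2 scale. Its software version and whether all 9 arrays were normalized together are not given in the sources used here. The values had no gaps, and their medians lay between 7.01 and 7.07 on every array. They were used as deposited, with no further normalization.

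Probe sets were named from the platform's annotation table, with symbols updated through gene identifiers from a RefSeq gene table of the assembly GRCm38.p6. Of the probe sets, 20393 had 1 gene symbol, 691 had several and 1606 were not listed. The identifiers of 20364 probe sets with 1 symbol were found in the RefSeq table. Probe sets with several or no genes named no gene. A gene took the value of its probe set with the highest mean over the 9 arrays, which applied to 4519 genes with more than 1 probe set. This left 12394 genes, of which 10032 reached log2 = 6 on at least 1 array and were analysed. No genome build is named for the deposited values, so no coordinates are given. The RefSeq table served only for names, for the chromosomes of genes and for which genes neighbour each other.

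Each group had 1 array, so a comparison of 2 arrays has no replicate check. Such comparisons are differences of log2 values, with counts of genes at least 2-fold (or 4-fold) higher or lower. They stand beside the same counts between the unstimulated arrays of different genotypes. The induction of a gene is its log2 value after LPS minus that of the unstimulated array of the same genotype. Among genes induced at least 4-fold in wild type, a lower induction in a knockout means a log2 induction at least 1 below that in wild type. Both knockouts were compared with the same wild-type arrays. Unchanged knockouts were therefore simulated 1000 times against them, with the spread of each gene from the fit described next, and unchanged groups 100 times for the overlap of calls.

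Tests across many genes were made with limma (lmFit and eBayes, no trend) in a fit of genotype and time, without interaction, to all 9 arrays. The genotypes served as replicates of a time point and the times as replicates of a genotype. This left 4 residual degrees of freedom, to which the prior added 8.39. A gene whose response differed between genotypes has a larger error in this fit. Tests were two-sided, with Benjamini-Hochberg adjustment over the 10032 genes and a threshold of 0.05. Nothing in the labels says that the arrays of a genotype came from separate mice or cultures, so p-values measure only the spread between these arrays, which may be technical. The fit was tested on simulated data with known changes in some of the 10032 genes. It recovered 100% of 100 genes changed by 0.5 (log2) for 1 h and for 4 h, 99% for MyD88 KO and 98% for TRIF KO. It recovered 100% of those changed by 1 in each comparison, with 11, 15, 18 and 16 false calls in the same order. The simulated changes were alike on all arrays of a condition, with independent noise on each array. These figures therefore do not cover responses that differ between genotypes or arrays that share mice.

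There were 26 gene lists, fixed before the data were examined. They covered the targeted genes, TLR4 signalling components, NF-kB subunits and inhibitors, immediate early transcription factors, inflammatory cytokines, chemokines not induced by interferon, type I interferon and interferon-stimulated genes, and CCCH zinc finger and mRNA decay proteins. Others held signalling feedback regulators, macrophage effector genes, antigen presentation and costimulation, lipid and cholesterol handling, cell cycle, oxidative stress response, macrophage identity, inflammasome and cell death, and reference transcripts. The remaining 9 held markers of neutrophils, B cells, T or NK cells, eosinophils, mast cells, dendritic cells, mesothelium, fibroblasts and erythroid cells. The median log2 difference of a list is described by its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Counts of members called by limma are given with adjustment over all genes and adjusted over the list alone.

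The rule for named genes was also fixed before the data were examined. It took the targeted genes and, for wild type at 1 h and 4 h, the 10 genes with the largest and the 5 with the smallest log2 difference. For each knockout it took the 10 genes with the largest loss of induction and up to 5 with the largest gain. It added up to 4 members of each list with the largest wild-type difference, any CCCH protein past 2-fold, the 10 genes with the smallest adjusted p per direction for LPS, and 5 per direction for each knockout. Genes named for other reasons are said to have been chosen after their values were seen. The grouping of arrays, the fit, the thresholds and all alternatives except 1 were likewise set before the data were examined. The added alternative was an F-test of time over the 3 times. The others were quantile normalization, centring on the reference transcripts, the mean of all probe sets of a gene, leaving out probe sets that may cross-hybridise, other filters on low values, a floor at log2 = 6, other fold thresholds, other choices of the induced genes and of what counts as a lower induction, a trended and robust prior, a fit without block, leaving out each array, genotype or time, and a fit to the arrays of 2 conditions. R 4.3.3 with limma 3.58.1 was used for all computations, and Python 3.11.15 with matplotlib 3.10.9 for the plots.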

Results

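Gene expression was measured in macrophages recruited into the peritoneal cavity of mice by thioglycollate broth, an irritant. The cells came from wild-type mice and from mice without MyD88 or without TRIF, the adaptor proteins that carry the signal of Toll-like receptor 4, the receptor of bacterial LPS. They were left unstimulated or received 100 ng/ml LPS for 1 h or 4 h. The 3 genotypes and 3 times made 9 groups with 1 array each, and the design asks which parts of the LPS response are kept when either adaptor is missing. There were no replicate arrays, and the number of arrays limits the precision of every value. Between the unstimulated arrays, 99% of the 10032 genes differed by less than 0.66 (log2) for MyD88 KO against wild type and by less than 0.47 for TRIF KO against wild type. Pairs of arrays correlated across genes at 0.986 to 0.998.

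The targeted gene Myd88 read 9.57 and 9.58 (log2) at 0 and 1 h in wild type and was 0.43 above the unstimulated level at 4 h. The TRIF KO arrays read 9.56, 9.54 and 9.96 at 0, 1 and 4 h. The MyD88 KO arrays read 9.30, 9.19 and 9.34. Across the 3 times the level in MyD88 KO fell by 0.44 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.00487, lower at 3 of 3 times), so most of the signal was still there. Where this probe set lies relative to the deleted part is not given in the sources used here, so it may check nothing. Ticam1, the gene of TRIF, had no probe set of its own and was not analysed here.

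After 1 h of LPS, wild-type macrophages had higher levels of cytokine and chemokine transcripts and of early regulators of transcription. Tnfsf9, a ligand of the TNF family, was higher by 4.06 (log2), the neutrophil-attracting chemokines Cxcl1 and Cxcl2 by 3.98 and 3.34, and Tnf and Il1b, key inflammatory cytokines, by 3.13 and 2.88. Nfkbiz, an inducible cofactor of NF-kB, was higher by 3.86 and the immediate early factor Egr1 by 2.82. Socs3, a brake on cytokine signalling, Il1a and the phosphodiesterase Pde4b were higher by 1.87, 1.78 and 1.61. In all, 24 genes were at least 2-fold higher and 0 lower, and 7 were at least 4-fold higher. Unstimulated cells of MyD88 KO and wild type differed 2-fold in 8 genes higher and 17 lower. The lowest differences at 1 h were -0.74 for Rgs2, a regulator of G protein signalling, and -0.65 for Thbd, thrombomodulin. Luc7l3, Trmt10b and Gadd45g followed with -0.63, -0.60 and -0.60.

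At 4 h the wild-type response was broader and included 13 of 34 interferon-stimulated genes at least 2-fold higher, against 1 at 1 h. Cxcl1 was higher by 4.25, the T cell-attracting chemokines Ccl5 and Cxcl10 by 3.80 and 3.03, and Acod1, the enzyme that makes itaconate, by 3.73. Il1b, Il6, Tnf and Tnfsf9 were higher by 3.32, 2.98, 2.92 and 2.82, Cxcl2 by 3.58 and Ptgs2, the inducible cyclooxygenase, by 2.93. Ccl5 differed by 0.02 at 1 h. In all, 123 genes were at least 2-fold higher and 46 lower, and 29 were at least 4-fold higher and 1 lower. That lower gene was Rgs2, at -2.17. Pparg, a nuclear receptor of lipid metabolism, was at -1.65, Thbd at -1.54, the chemokine receptor Cxcr4 at -1.51 and the cannabinoid receptor Cnr2 at -1.46. Il6 and Cxcl5 started at 3.97 and 4.11, near the low end of the arrays, where a log2 difference understates the change.

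**Figure D1:**
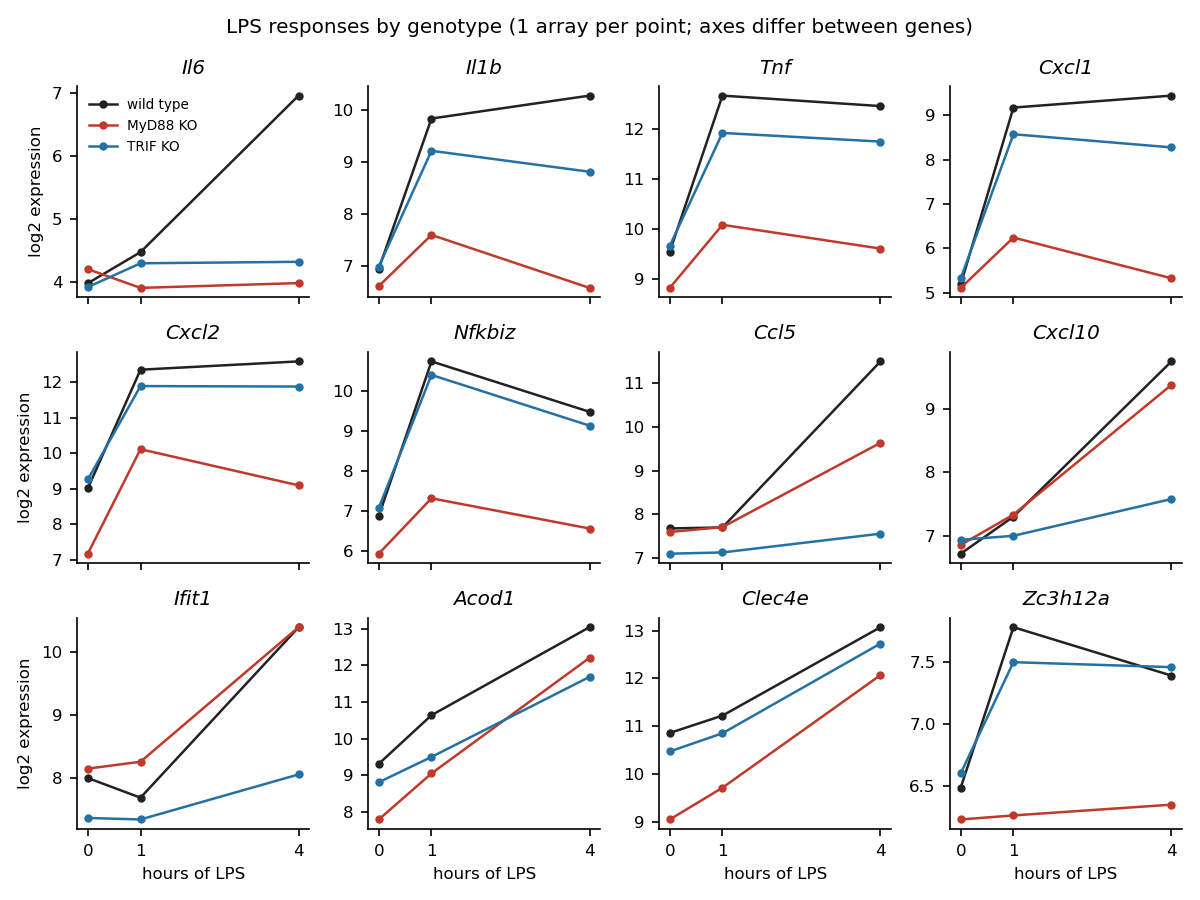
Log2 expression of 12 genes (vertical axes, which differ between genes) against hours of LPS (horizontal axes) in wild type, MyD88 KO and TRIF KO, with 1 array per point and no error bars. Il6 was higher by 2.98 at 4 h in wild type alone, Ccl5, Cxcl10 and Ifit1 stayed low in TRIF KO, and Acod1 and Clec4e were higher at 4 h in all 3 genotypes.

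In MyD88 KO macrophages most of the inflammatory cytokine response was missing at 4 h. The log2 induction of Il1b was -0.03 against 3.32 in wild type, that of Il6 -0.22 against 2.98, that of Cxcl1 0.22 against 4.25 and that of Ccl3, a monocyte-attracting chemokine, -0.34 against 2.80. Ptgs2, Il1a and Cxcl5 stood at 0.09, 0.09 and -0.07, and Tnf, Tnfsf9 and Nfkbiz kept 0.79, 0.49 and 0.63. Other genes kept their induction over the unstimulated level. Acod1 was induced by 4.41 and Clec4e, a receptor for mycobacterial glycolipid, by 3.02, against 3.73 and 2.21 in wild type, and Marcksl1, Ifit2 and Nfkbie by 2.85, 2.18 and 2.04. Acod1, Clec4e and Nfkbie started lower than in wild type (differences of -1.52, -1.81 and -1.07), and their levels at 4 h were still below it (-0.84, -1.001 and -1.06). Of the 29 genes induced 4-fold in wild type at 4 h, 16 had a lower induction in MyD88 KO and 13 lay within 1 of wild type. At least 2-fold higher than in unstimulated MyD88 KO cells were 43 genes, and 1 was lower.

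At 1 h the early response in MyD88 KO was smaller but present. Of the 7 genes induced 4-fold in wild type, 6 had a lower induction in MyD88 KO. Cxcl1 was induced by 1.13 and Nfkbiz by 1.38, against 3.98 and 3.86 in wild type. Tnfsf9, Il1b, Tnf and Egr1 were induced by 1.74, 0.98, 1.26 and 1.45. The remaining gene was Cxcl2, with 2.94 against 3.34. Its unstimulated level was lower than in wild type (-1.84), so that its level at 1 h was also below that of wild type. With no replicate, the size of these differences has no error, and unchanged knockouts gave 0.93 genes with a lower induction at 1 h and 2.17 at 4 h on average over 1000 simulations. The share at 4 h was 55.2% and moved by over 1.5 times under 1 other choice of genes. It was 30.0% (3 of 10) among genes induced 4-fold on average over the genotypes. That average includes the knockout itself, so genes that lost their induction there tend to drop out. The share was 79.3% when stimulated levels were compared directly.

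TRIF KO macrophages kept much of the 1 h response and showed low induction of interferon-stimulated genes at 4 h. Ccl5 was induced by 0.46 against 3.80 in wild type, Cxcl10 by 0.64 against 3.03, and the interferon-induced antiviral genes Ifit1 and Ifit2 by 0.69 and 0.31 against 2.39 and 2.03. Il6 was induced by 0.40 against 2.98. Ptgs2, Il1b, Ccl3 and Cxcl5 kept part of their induction, at 1.27, 1.82, 1.34 and 0.92. Clec4e, at 2.25, was the 1 gene of the 29 with an induction above that in wild type. Of the 29 genes, 15 had a lower induction in TRIF KO and 14 lay within 1. Higher by 2-fold at 4 h were 41 genes and lower 5.

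At 1 h, 6 of the 7 genes induced 4-fold in wild type were within 1 in TRIF KO. Cxcl1 was induced by 3.24, Nfkbiz by 3.32, Cxcl2 by 2.63, Tnf by 2.26, Il1b by 2.22 and Egr1 by 2.12, each below its value in wild type. Tnfsf9, at 1.88 against 4.06, was the exception. The share at 4 h was 51.7%, and it moved by over 1.5 times under 1 other choice. It was 30.0% (3 of 10) among genes induced 4-fold on average over the genotypes, an average that includes TRIF KO itself.

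By the size rule, the 29 genes fell into 4 classes. Il6, Il1b, Il1a, Cxcl1, Cxcl5, Ccl3, Ccl5, Ptgs2 and Tnfsf9 were among 12 with a lower induction in both knockouts. Cxcl2, Tnf, Nfkbiz and Ptges, the inducible prostaglandin E synthase, were lower in MyD88 KO alone, and Cxcl10, Ifit1 and Ifit2 in TRIF KO alone. Acod1, Fpr2, Gpr84, Icam1, Clec4e and Nfkbie were among 10 lower in neither. The classes rest on induction over the unstimulated level of the same genotype, not on the level reached. At 4 h in MyD88 KO, Fpr2, Gpr84, Clec4e and Nfkbie stood at -2.42, -1.53, -1.001 and -1.06 against wild type. Acod1 stood at -0.84 there and at -1.36 in TRIF KO. Several genes lay near the limit of -1 and could change class: in TRIF KO Icam1 at -0.99, Cxcl2 at -0.96 and Tnf at -0.83, and in both knockouts Pde4b, at -1.04 and -1.02, and Traf1, at -1.10 and -1.07. Ptges and Icam1 were chosen after their values were seen. Independent lists of 16 and 15 among 29 genes would share 8.28, and unchanged knockouts compared with the same wild-type arrays shared 0.72 on average. The covariance of the losses across genes was 0.380, against a mean of 0.178 and a 95th percentile of 0.366 in the simulation, while their correlation, 0.408, lay below the simulated mean of 0.446. Both knockouts were set against the same wild-type arrays, which cannot be split, so part of the excess may come from these shared controls.

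**Figure D2:**
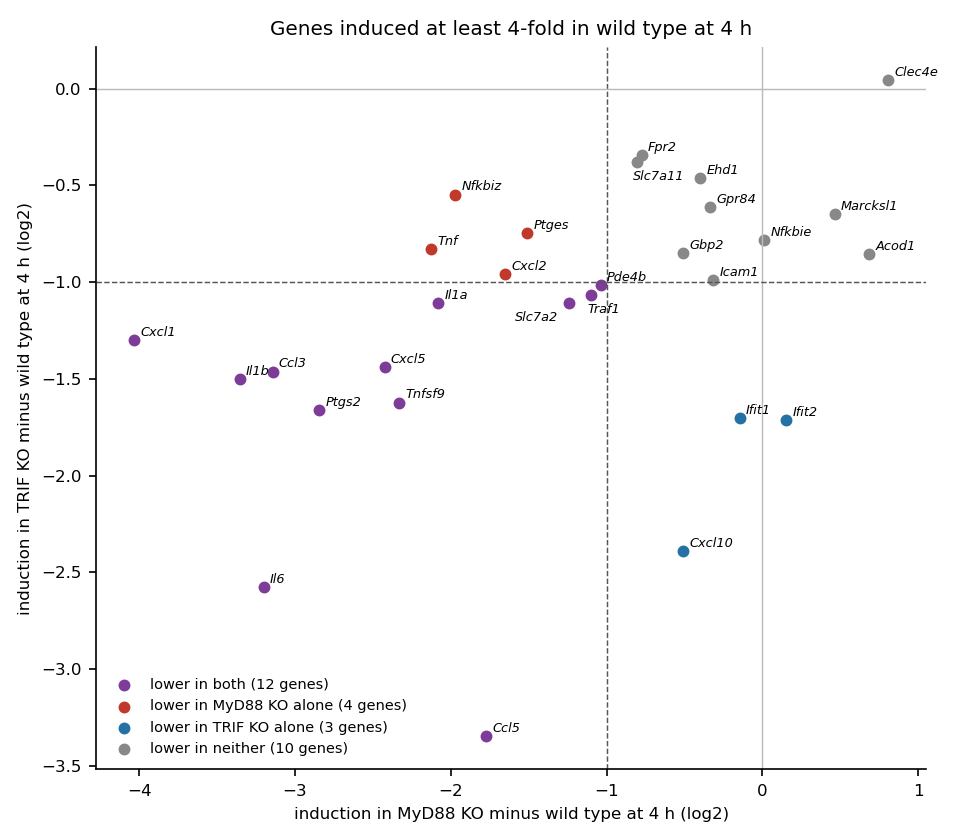
Each point is 1 of the 29 genes induced at least 4-fold in wild type at 4 h, placed by its log2 induction in MyD88 KO minus wild type (horizontal) and TRIF KO minus wild type (vertical), from 1 array per group. Dashed lines mark -1, the limit for a lower induction; 12 genes lie beyond both limits, with Cxcl10, Ifit1 and Ifit2 beyond that of TRIF KO alone and Cxcl2, Tnf, Nfkbiz and Ptges beyond that of MyD88 KO alone.

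The gene lists differed in which knockout had the lower medians, a difference that was not tested. At 4 h, the 34 measured interferon-stimulated genes had a median log2 difference of 0.57 in wild type, 0.70 in MyD88 KO and 0.10 in TRIF KO, with 13, 11 and 1 members at least 2-fold higher. The induction in TRIF KO was below that in MyD88 KO for 32 of the 34. Gbp2, a guanylate-binding protein, was induced by 2.07, 1.56 and 1.22 in the same order. The transcript of interferon beta itself was below the filter on low values on every array and was not analysed. Across genotypes, 21 members rose and 1 fell at 4 h by limma with Benjamini-Hochberg adjustment over all genes, and 25 and 1 adjusted over the list alone. Against wild type, 0 members passed in TRIF KO over all genes, while 13 were lower adjusted over the list alone.

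The 16 inflammatory cytokines had a median of 0.48 in wild type, 0.05 in MyD88 KO and 0.15 in TRIF KO at 4 h, with 6, 0 and 4 members at least 2-fold higher. The induction was below that in wild type for 15 of the 16 in each knockout, with median differences of -0.42 and -0.34. By limma, 6 of them rose at 4 h over all genes and 7 adjusted over the list alone. In MyD88 KO 7 were lower on average over the 3 times, and 10 adjusted over the list alone. The list median in unstimulated MyD88 KO was 0.05 above wild type, so these calls need not hold before LPS. Il1b was higher by 1.70 ± 0.397 (SE) on average over the genotypes (limma, Benjamini-Hochberg adjusted p = 0.0140), with a difference near 0 in MyD88 KO. The 11 chemokines not induced by interferon had medians of 0.92, 0.08 and 0.64, with 6 rising by limma over all genes and 7 adjusted over the list alone. These medians were 0.47, 0 and 0.17 with low values raised to log2 = 6, and 1.92, 0.09 and 0.82 among members with a mean of at least log2 = 7. The cytokine medians under that filter were 0.55, 0.11 and 0.36. Cxcl2 rose by 2.71 ± 0.221 (limma, Benjamini-Hochberg adjusted p = 9.30e-06, higher in 3 of 3 genotypes). In MyD88 KO 3 chemokines were lower and 2 higher on average over the times, or 1 higher after centring on the reference transcripts. Adjusted over the list alone there were 6 lower and 2 higher.

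The NF-kB subunits and inhibitors had higher medians at 4 h in all genotypes, though not each member was higher in each. The medians were 1.18, 0.66 and 0.74 over 14 genes, with 8, 5 and 5 at least 2-fold higher, and 13 rose on average over the genotypes by limma, also 13 adjusted over the list alone. Nfkb2 rose by 1.30 ± 0.0954 (limma, Benjamini-Hochberg adjusted p = 3.59e-06), and Nfkbie by 1.77. In MyD88 KO 10 members were lower on average over the 3 times, and 12 adjusted over the list alone, against 0 in TRIF KO. Among 23 macrophage effector genes the medians were 0.64, 0.43 and 0.66. By limma 16 rose and 1 fell (0 after centring), and 17 and 1 adjusted over the list alone; 11 were lower in MyD88 KO, 17 adjusted over the list alone, and 18 after centring on the reference transcripts. Fpr2, a formyl peptide receptor, was induced by 2.75, 1.97 and 2.40, and Slc7a2, an arginine transporter, by 2.10, 0.86 and 1.00. The oxidative stress list had medians of 0.42, 0.56 and 0.55 over 11 genes, and 9 rose by limma, also 9 adjusted over the list alone. Slc7a11, the cystine transporter, rose by 1.84, and Srxn1, Sqstm1 and Txnrd1 by 0.72, 0.73 and 0.71. In MyD88 KO 6 of these genes were lower on average over the times, and 9 adjusted over the list alone.

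**Figure D3:**
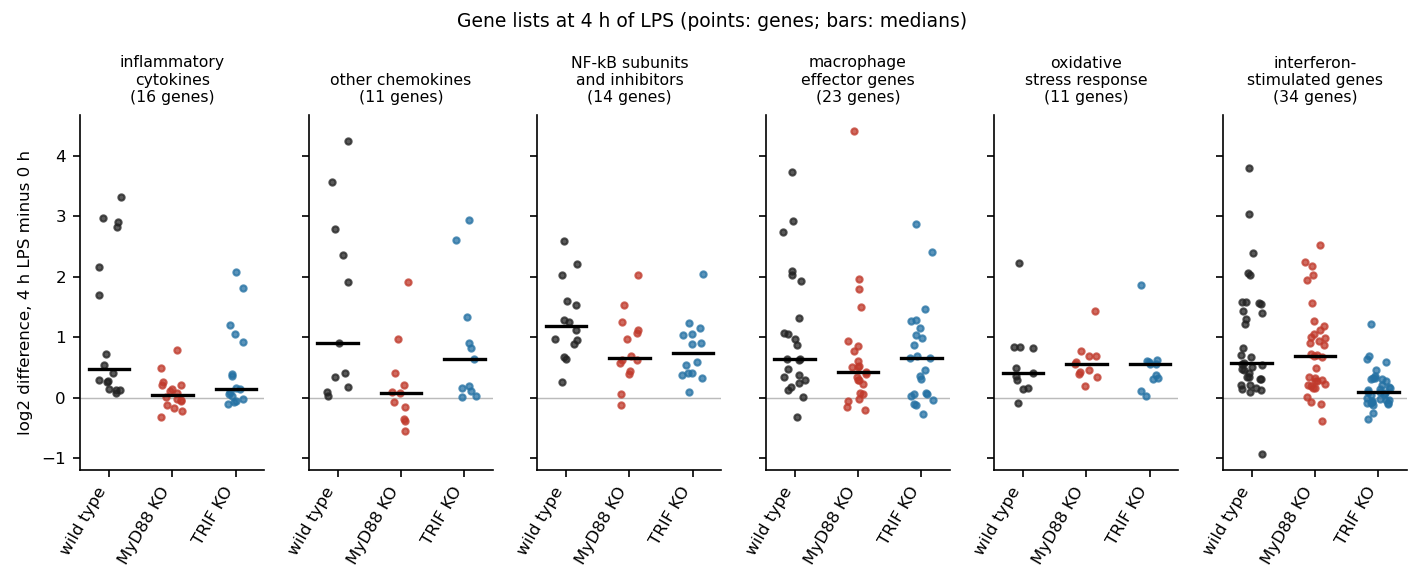
Log2 difference between 4 h of LPS and 0 h (vertical axis) for the measured members of 6 gene lists in wild type, MyD88 KO and TRIF KO, with 1 array per group; points are genes and bars are medians. The interferon-stimulated genes had medians of 0.57, 0.70 and 0.10 and the inflammatory cytokines 0.48, 0.05 and 0.15.

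Regulators of transcription and mRNA decay moved at 1 h and at 4 h. Of 19 immediate early transcription factors, 5 rose at 1 h by limma and 11 adjusted over the list alone; at 4 h 5 rose, and 7 rose and 1 fell adjusted over the list alone. Maff was induced by 1.74 in wild type at 4 h, 0.76 in MyD88 KO and 0.92 in TRIF KO. Among 9 CCCH zinc finger and mRNA decay proteins, Zfp36, which binds AU-rich elements, was induced by 1.39, 0.65 and 1.29 at 1 h. Zc3h12a, an endonuclease that degrades cytokine mRNAs, was induced by 1.29 at 1 h in wild type, 0.03 in MyD88 KO and 0.89 in TRIF KO, and by 0.90, 0.12 and 0.85 at 4 h. Zfp36l1 and Zfp36l2 fell by 0.35 and 0.42 at 4 h. By limma 1 member rose at 1 h and 2 adjusted over the list alone; at 4 h 2 rose and 3 fell under both adjustments, or 1 and 1 after centring on the reference transcripts. Of 12 signalling feedback regulators 2 rose at 1 h and 5 adjusted over the list alone; at 4 h 3 rose and 1 fell, and 5 and 1 adjusted over the list alone. The phosphatase Dusp2 rose by 0.68 at 1 h, and Rgs1 fell by 0.76 at 4 h.

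The fit across the 3 genotypes called 29 genes higher and 0 lower at 1 h by limma, with 543 genes at an unadjusted p under 0.05. Cxcl2 rose by 2.97 ± 0.221 (SE; limma, Benjamini-Hochberg adjusted p = 9.10e-05) and Egr1 by 2.13 ± 0.178 (limma, Benjamini-Hochberg adjusted p = 0.000178), both higher in 3 of 3 genotypes. Ier3, the phosphatase Dusp1, the growth inhibitor Btg2, Cd83, Zfp36, Junb, Nfkbiz and Nfkbia, the main inhibitor of NF-kB, rose by 1.12, 1.15, 0.77, 0.96, 1.11, 0.98, 2.86 and 0.81. Il1b, at 2.03, did not pass (limma, Benjamini-Hochberg adjusted p = 0.0683), with inductions of 2.88, 0.98 and 2.22. The count lay between 7 (without the wild-type 1 h array) and 46 (without the MyD88 KO arrays) when arrays were left out, and Nfkbiz and Nfkbia were not called without the wild-type arrays or the wild-type 1 h array. A fit without block called 1 gene, and raising low values to log2 = 6 left 10.

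At 4 h the same fit called 463 genes higher and 715 lower, most by small amounts: the median was 0.46 for those that rose and -0.33 for those that fell, and 61 and 5 passed 2-fold. Gpr84, a receptor for medium-chain fatty acids, rose by 2.35 ± 0.0943 (SE; limma, Benjamini-Hochberg adjusted p = 5.86e-08, higher in 3 of 3 genotypes). Acod1, Clec4e, Fpr2, Ehd1, Serpinb2, Mmp14, Olr1, Sod2 and Ampd3 rose by 3.67, 2.49, 2.38, 1.79, 1.73, 1.47, 1.43, 1.33 and 1.31. Abcd2, a peroxisomal transporter of fatty acids, fell by 1.07 (limma, Benjamini-Hochberg adjusted p = 3.64e-06, lower in 3 of 3 genotypes). Slc46a3, the monocyte chemokine receptor Ccr2, Socs6, Tmem37, the lysosomal phospholipase Pla2g15, Cd300lf, Wwp1, Rcbtb2 and Daglb fell by 1.00, 0.92, 0.85, 0.78, 0.73, 1.01, 0.66, 0.85 and 0.87. Of the 29 genes higher at 1 h, 21 were also higher at 4 h, against 1.34 for independent lists and at most 1 in 100 simulations without change. Such simulations leave few genes to be called, so their overlap is near 0 by design. The covariance of the estimates was 0.0114 (simulated 0.00299) and their correlation 0.439 (simulated 0.499), and part of the excess may come from the shared unstimulated arrays. With arrays left out, the lowest counts were 283 higher (without the wild-type 4 h array) and 245 lower (without the TRIF KO arrays). Centring on the reference transcripts left 459 lower.

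On average over the 3 times, MyD88 KO differed from wild type in genes that LPS induces, in genes that it lowers and in others. Gdpd3, a lysophospholipase D, and Cap1, an actin regulator, were higher at 3 of 3 times. Unstimulated Gdpd3 read 10.63 against 7.71 in wild type (limma across times, SE 0.0806, Benjamini-Hochberg adjusted p = 4.28e-10), and Cap1 was higher by 2.40 ± 0.0896 (limma, Benjamini-Hochberg adjusted p = 1.22e-08). Ifi44l, an interferon-stimulated gene, Itgax, the integrin CD11c, and Arg1, arginase, rose by 1.599, 1.09 and 0.92. Fpr2, Lcn2, Gpr84, Calml4 and Cxcl16 fell by 1.91, 1.34, 1.33, 1.21 and 1.04. In all, limma called 457 genes higher and 269 lower, of which 9 and 23 passed 2-fold. Centring on the reference transcripts turned this split to 127 higher and 797 lower, and it moved the median of all genes to -0.13 (-0.126). The direction of small differences therefore depends on the scaling, while the 10 genes named here kept theirs. The centring used the median level of the reference transcripts on each array. Their median differences in MyD88 KO from wild type were -0.0225, 0.105 and 0.005 at 0, 1 and 4 h. How much of the turned split rests on that way of centring was not tested. Ifi44l, low in wild type at 4.66, was not called when low values were raised to log2 = 6. Of the 463 genes higher at 4 h of LPS, 161 were lower in MyD88 KO, against 12.4 for independent lists, and of the 715 lower at 4 h 183 were higher, against 32.6. Simulations without change shared at most 1 gene in either direction, and the covariance of the estimates was -0.0236, against 2.7e-06 in the simulations. Few genes can be called without change, so the simulated overlap is near 0 by design. A gene that loses its response to LPS in MyD88 KO can enter both lists. These overlaps are therefore not separate from the lost response. The lowest counts with arrays left out were 162 higher and 116 lower, both without the 1 h arrays.

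Other lists moved in MyD88 KO as well. Of 18 cell cycle genes, 9 were higher by limma and 10 adjusted over the list alone, or 6 after centring on the reference transcripts. Mcm6, a replication helicase subunit, rose by 0.70 and Rrm2, a ribonucleotide reductase subunit, by 0.87, and 1 list member was higher in TRIF KO (0 after either other scaling). Of the interferon-stimulated genes 8 were higher and 1 lower, 9 and 1 adjusted over the list alone, and 4 and 1 after that centring. Markers of other cells moved too. The fibroblast markers Col3a1 and Dcn, collagen and decorin, rose by 1.45 and 0.57 in MyD88 KO and by 1.02 and 0.69 in TRIF KO. Col3a1 read 5.42, 5.34 and 5.10 in wild type, below log2 = 6, where the size of a difference is uncertain. Of 5 fibroblast markers 3 were higher in each knockout, also 3 adjusted over the list alone, and their median at 0 h was 0.43 and 0.47 above wild type. Of 6 B cell markers 2 were lower in each knockout, and 3 in MyD88 KO and 5 in TRIF KO adjusted over the list alone. Cd79a, part of the B cell receptor, fell by 0.49 and 0.56.

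TRIF KO differed from wild type in fewer genes. Gdpd3 and Cap1 were again highest, at 3.46 and 2.34. Gdf3, a growth factor of the TGF-beta family, Gnb1, a G protein subunit, and Itgax rose by 1.44, 1.34 and 1.28. Npy, neuropeptide Y, fell by 2.28, the cytoskeletal adaptor Fblim1 by 1.98, the glutaminyl cyclase Qpct by 1.87, the bridging protein of phagocytosis Mfge8 by 0.88 and Trim34a by 0.86. Limma called 118 genes higher and 42 lower, of which 8 and 5 passed 2-fold; Qpct had a Benjamini-Hochberg adjusted p of 5.44e-08 by limma and was lower at 3 of 3 times. With MyD88 KO it shared 82 higher and 28 lower genes, against 5.38 and 1.13 for independent lists and at most 1 in 100 simulations of unchanged knockouts. Unchanged knockouts leave few genes to be called, so that simulated overlap had little room. The covariance of the 2 sets of estimates was 0.0161, against 0.00301 in these simulations, their correlation 0.619, against 0.5004, and part of the excess may come from the shared wild-type arrays. The lowest counts with arrays left out were 25 and 14, both without the 1 h arrays. After centring on the reference transcripts 73 were higher, and with low values raised to log2 = 6 there were 72 higher and 24 lower.

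Some of these differences held at each time, with and without LPS, though their size could change with it: Cxcl2 in MyD88 KO was at -1.84, -2.24 and -3.49 at 0, 1 and 4 h. In MyD88 KO, 14 genes differed at least 2-fold in 1 direction at all 3 times, 7 higher and 7 lower, or 10 with low values raised to log2 = 6. In TRIF KO there were 9, with 5 higher and 4 lower. Gdpd3, Cap1 and Itgax, all higher, were in both sets, against 0.0126 genes for independent sets. Gdpd3 and Itgax lie on the same chromosome, in 1 run of 26 called MyD88 KO genes over 278 measured genes, so these 2 genes may not be independent. In the RefSeq gene table of GRCm38.p6, 0 of the 14 genes (2 of 16 after centring on the reference transcripts) lay on the chromosome of Myd88, which holds 5.57% of all genes, and 1 of the 9 on that of Ticam1, which holds 5.01%. This was Qpct, and 36.5% of random sets of 9 genes held as many. Among all genes called by limma in MyD88 KO, Myd88 itself lay in a run of 11 over 71 measured genes. Cap1 had another probe set, which read 2.53 higher in MyD88 KO and 2.57 in TRIF KO on average over the times.

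Before any LPS was added, MyD88 KO cells had lower levels of some of the genes that LPS induces. Cxcl2 was at -1.84 against unstimulated wild type, Clec4e at -1.81, Fpr2 at -1.64, Acod1 at -1.52, Gpr84 at -1.20, Cxcl16 at -1.12 and Nfkbie at -1.07. In TRIF KO the same genes stood at 0.25, -0.39, 0.32, -0.50, -0.17, -0.10 and 0.21. Of 41 genes at least 2-fold higher in TRIF KO cells at 4 h, 36 were lower in unstimulated MyD88 KO, with a median of -0.59, and 12 in unstimulated TRIF KO, with a median of 0.07. This set was chosen after these differences were seen. The median of the NF-kB list was -0.27 in unstimulated MyD88 KO and 0.19 in TRIF KO, that of the macrophage effector list -0.30 and 0.02, and that of the interferon-stimulated genes 0.18 and -0.07. The inflammatory cytokines, at 0.05 and 0.05, and the other chemokines, at -0.03 and 0.12, were not lower as lists in MyD88 KO beyond matched random lists (percentiles 63.7 and 22.6). The B cell markers stood at -0.28 and -0.46 in the same cells, with Cd79b at -1.01 and -0.97, Cd79a at -0.74 and -0.66 and Ms4a1, chosen after its values were seen, at -0.44 and -0.69. These are differences between single arrays with no test.

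**Figure D4:**
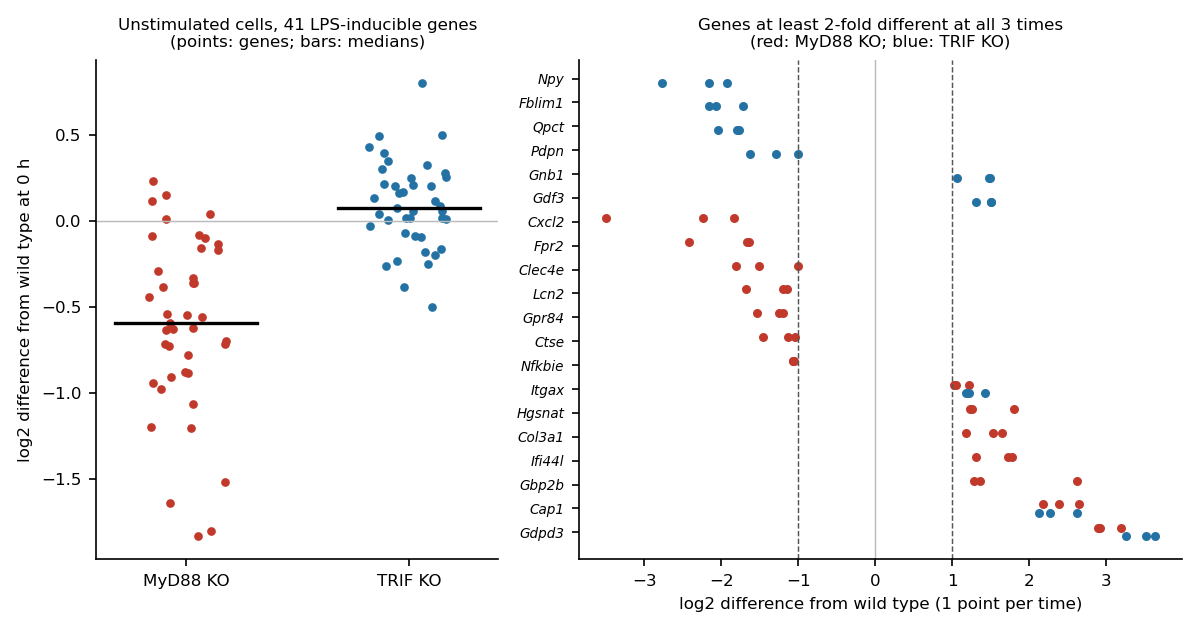
Left, log2 difference from wild type in unstimulated cells (vertical axis) for the 41 genes at least 2-fold higher in TRIF KO at 4 h; points are genes and bars are medians, -0.59 for MyD88 KO and 0.07 for TRIF KO. Right, log2 difference from wild type (horizontal axis) at 0, 1 and 4 h, 1 point per time, for the genes at least 2-fold different at all 3 times in MyD88 KO (14) or TRIF KO (9), with Gdpd3, Cap1 and Itgax in both.

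Members of the remaining lists moved as well. Of 15 TLR4 signalling components 3 rose and 1 fell at 4 h by limma, and 4 and 1 adjusted over the list alone. The LPS co-receptor Cd14 and the kinase Ikbke rose by 0.70 and 0.90, and the receptor Tlr4 fell by 0.40. Map3k8, a kinase upstream of ERK, fell by 0.69 in MyD88 KO across times. Of 20 antigen presentation and costimulation genes 7 rose and 14 adjusted over the list alone, with Cd40, Icosl, Cd274 and Tap1 at 1.11, 0.88, 0.66 and 0.38. Of 10 inflammasome and cell death genes 5 rose under both adjustments and 2 fell adjusted over the list alone; Nlrp3, the sensor of the inflammasome, Casp4, Cflar and Fas rose by 1.08, 1.03, 0.84 and 0.78. Of 16 lipid genes 3 rose and 2 fell, and 4 and 3 adjusted over the list alone. Ch25h, cholesterol 25-hydroxylase, and the cholesterol exporter Abca1 rose by 1.02 and 0.81, while Pparg and Abcg1 fell by 1.00 and 0.46. Among cell cycle genes 1 rose (Mki67, 0.61) and 2 fell (Mcm6 and Pcna, by 0.46 and 0.27, 1 of them after centring) at 4 h, and 1 and 3 adjusted over the list alone. Of 17 macrophage identity genes 1 rose and 2 fell under both adjustments, and Mertk, a receptor for apoptotic cells, and Fcgr1, a receptor for IgG, fell by 0.89 and 0.75.

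Markers of other cell types were also followed through the LPS response. The B cell markers had medians of -0.17 at 1 h and -0.21 at 4 h in wild type, with Cd79b at -0.54 and -0.95. The medians were 0.09 and -0.015 in MyD88 KO and 0.03 and 0.02 in TRIF KO. Cd79b at 4 h was at -0.002 in MyD88 KO and -0.16 in TRIF KO. At 4 h, by limma over all genes and adjusted over the list alone, 1 of 9 neutrophil markers fell (Mmp8, by 0.56) and 1 of 6 B cell markers (Cd22, by 0.23; 0 after either other scaling). None passed in either adjustment among 5 T or NK cell, 2 eosinophil, 5 mast cell, 4 dendritic cell, 3 mesothelium, 5 fibroblast and 3 erythroid markers. Their wild-type medians lay between 0.079 (erythroid) and 0.24 (dendritic cell). Between genotypes, the mesothelium markers had medians of 0.31 in MyD88 KO and 0.23 in TRIF KO above wild type at 0 h, and 1 of them, Krt19, was higher in MyD88 KO by 0.24 (limma, Benjamini-Hochberg adjusted p = 0.0459; not called after centring), or 3 adjusted over the list alone. The dendritic cell list held Itgax, which was higher in both knockouts (1 member in each, and 2 in MyD88 KO adjusted over the list alone or after quantile normalization). In TRIF KO 1 neutrophil and 1 mast cell marker were higher adjusted over the list alone and 0 over all genes. Of 10 reference transcripts 0 moved with LPS, and 1 was higher in MyD88 KO (0 higher and 1 lower after centring), or 3 adjusted over the list alone.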

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

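Of the tests below, those of scaling, random gene lists, B cells, MyD88 signalling, Qpct, stretches of DNA, the choice of induced genes, a compressed range and the F-test of time were chosen only after the result was seen. Among the named genes, the sign of the induction in a knockout was set against that in wild type. Of 572 such comparisons of 143 genes, 17 in 15 genes (2.97%) went in opposite directions by more than the spread of a difference on both sides, where unchanged genes would give 5.03%. Each rests on 1 array per group, and the difference between genotypes was not tested. At 1 h in MyD88 KO, the log2 induction was 0.2262 for Calml4 (wild type -0.1909), 0.1912 for Dcn (-0.1727), 0.3413 for Gbp2 (-0.4515), -0.2783 for Ifi44l (0.1837), 0.4331 for Ighm (-0.284), -0.2048 for Ngp (0.2561), 0.2362 for Qpct (-0.2087), 0.2005 for Rrm2 (-0.3039) and 0.1914 for Tbp (-0.236). At 1 h in TRIF KO it was 0.1771 for Rrm2 (-0.3039) and -0.1636 for Pdgfra (0.1519). At 4 h it was -0.1518 for Krt8 (0.1437) and 0.1955 for Qpct (-0.1705) in MyD88 KO. In TRIF KO at 4 h it was -0.1935 for Ccr3 (0.196), 0.3921 for Col3a1 (-0.3133), 0.1664 for Gnb1 (-0.2722) and 0.3858 for Npy (-0.4483).

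Some genes that LPS induces were lower in unstimulated MyD88 KO cells: 41 genes chosen on the TRIF KO arrays had a median of -0.5942 (bootstrap 95% interval -0.7178 to -0.3599). Array-wide scaling is argued against by the reference transcripts, at -0.02254. Of matched random lists 0% lay as low (lowest -0.1396). Such lists hold genes that need not move together, and the 41 genes were chosen after the differences were seen. The random lists therefore cannot exclude chance in the choice of genes. Fewer B cells in the preparation are argued against by TRIF KO, where the same 41 genes stood at 0.07273 (0.01609 to 0.2024) while the B cell markers were low in both knockouts (medians -0.4584, and -0.2785 in MyD88 KO). Signalling through MyD88 without added LPS may account for the -0.5942, and whether from traces of ligand in the cultures or from the cells' own ligands cannot be told apart, since no array separates them. With 1 unstimulated array per genotype, a difference between the preparations remains open too.

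Gdpd3, Cap1 and Itgax differed at least 2-fold from wild type at each time in both knockouts. By that rule 17 other genes did so in 1 knockout only, though some also differed in the other. Gdf3, Gnb1 and Fblim1, which met the rule in TRIF KO, were also called by limma in MyD88 KO. Noise in the shared wild-type arrays gave at most 0 such genes in 1000 simulations of unchanged knockouts. The spread between arrays (median 0.0879, log2) leaves little room for a 2-fold shift at each time, so this 0 was largely fixed by design. A difference of the wild-type preparation lasting over all times would shift both knockouts alike. It was not simulated and stays open. A strain variant under a single probe set is argued against for Cap1, whose other probe set gave at least 1.055 times the log2 difference, and stays open for Gdpd3 and Itgax, which had 0 other probe sets. DNA flanking the targeted gene is argued against for 16 of the 17 genes, which lie on other chromosomes, and stays open for Qpct, 68 measured genes from Ticam1. It also stays open for smaller differences near Myd88, which lay in a run of 11 called MyD88 KO genes over 71 measured genes. Stretches of DNA of another mouse strain elsewhere may contribute and stay open. In MyD88 KO 610 of the 726 called genes had the next called gene on the chromosome within 25 measured genes. The upper limits of draws from the LPS calls and of random draws were 608 and 614. In TRIF KO there were 59 of 160, with limits of 62 and 61. Random draws averaged 602.4 and 51.18, so the count in MyD88 KO was high for random genes too. In MyD88 KO Gdpd3 and Itgax shared 1 run of 26 such called genes, and Fblim1 and Gnb1 a run of 12.

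Of the 29 genes induced 4-fold in wild type at 4 h, 16 had a lower induction in MyD88 KO and 15 in TRIF KO. Choosing the genes on the wild-type arrays may contribute and stays open: among genes chosen on the third genotype at 4 h the share with a lower induction was at least 0.703 times as large, but from 4 of 8 genes for MyD88 KO and 4 of 11 for TRIF KO, and at 1 h for TRIF KO from 0 of 1. In MyD88 KO a compressed range of the arrays as the whole cause is argued against by the scatter of the induction. Around a common share of the induction in wild type it was 1.189 (log2), against array noise of 0.173, or 0.7178 with each gene's own spread. In TRIF KO the scatter was 0.6537, above array noise of 0.1793 but below the 0.7071 from each gene's own spread. That own spread also holds differences between genotypes, so the scatter does not decide for TRIF KO. The oxidative stress list kept more than the common share in MyD88 KO, by a median of 0.3106 (0.2477 to 0.3846). It did so in TRIF KO too, by 0.1724 (0.1263 to 0.2767). In both knockouts this list argues against a compressed range as the whole cause. As part of the cause a compressed range cannot be told apart from loss of the adaptor, since either would lower many genes (any lower induction in 24 and 28 of the 29). Loss of the adaptor is the biological explanation that the design names, and with 1 array per group it was not tested apart from differences between preparations.

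Other splits of the arrays were counted for each test across genes. For the 6 arrays of 2 conditions there are 10 splits, too few for a share under 0.05, and 1 (the real split) gave as many genes in each case. The real splits called 29 genes for LPS at 1 h, 1178 at 4 h, 726 for MyD88 KO and 160 for TRIF KO, and the highest of the other splits 0, 0, 0 and 0. For the F-test of time, an alternative chosen after seeing the data, 2 of the 36 assignments of the times within genotypes gave as many genes, so chance is not excluded by this count. The real assignment called 1065 genes and the highest other 1152. The latter exchanged the 0 h and 1 h arrays of MyD88 KO and left the other 7 in place. The assignments that kept every 4 h array in place called 726 to 1152 genes, and all others at most 1.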

How the results depend on the processing

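The F-test of time was chosen after seeing the data; the other alternatives were set before. No paired analysis was possible because each group had 1 array and the labels carry no replicate numbers; genotype and time served as blocks instead. Signal near background limits low genes: a floor at log2 = 6 shrinks their differences. Under 7 alternatives the 4 h median of the interferon-stimulated genes lay within 0.5458 to 0.6033 in wild type, 0.6865 to 0.7098 in MyD88 KO and 0.06315 to 0.1229 in TRIF KO. The cytokines ranged over 0.3515 to 0.5491, 0.03287 to 0.1136 and 0.1196 to 0.3557, and the other chemokines over 0.4676 to 1.92, 0 to 0.09421 and 0.1693 to 0.8237. The share of knockout genes on the chromosome of the targeted gene was 0% to 12.5% for MyD88 KO (12.5% on centring, 0% otherwise) and 11.11% to 12.5% for TRIF KO.

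With low values raised to log2 = 6, limma called 10 genes higher at 1 h (29 as reported), 178 lower in MyD88 KO (269), and 72 higher and 24 lower in TRIF KO (118 and 42). Without block, in which the differences between genotypes or times enter the error, it called 1 higher at 1 h, 150 higher and 158 lower at 4 h (463 and 715), 72 and 23 in MyD88 KO (457 and 269) and 50 and 16 in TRIF KO. Fits to only the arrays of the 2 conditions called 52 higher and 1 lower at 1 h, 422 lower at 4 h and 271 higher in MyD88 KO. Centring on the reference transcripts left 459 lower at 4 h, 127 higher and 797 lower in MyD88 KO and 73 higher in TRIF KO; it subtracts the reference median of each array, so small differences change sides. Wild-type counts at 1.5-fold were 50 higher and 8 lower at 1 h and 255 and 279 at 4 h, and at 4-fold 7 higher at 1 h and 29 and 1 at 4 h.

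Among genes induced 4-fold on average over the genotypes, 30% (3 of 10) had a lower induction at 4 h in MyD88 KO and 30% (3 of 10) in TRIF KO. The average includes each knockout, which by itself favours a lower share. Stimulated levels compared directly gave 79.31% for MyD88 KO, and genes chosen on the other knockout 0% (0 of 1) for TRIF KO at 1 h. The median of the interferon-stimulated genes in wild type at 1 h turned from -0.0466 to 0.09785, that of antigen presentation in MyD88 KO at 1 h from 0.0305 to -0.03393 and that of the reference transcripts in wild type at 1 h from -0.114 to 0.03045 on centring, and that of oxidative stress in TRIF KO at 1 h from 0.0372 to -0.001556 on quantile normalization; the cause was not tested. Of 6408 other values of single genes and lists, 6216 stayed the same, 163 moved, 25 fell short of the threshold and 4 reversed.

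Arrays were left out singly, by genotype or by time, and a lone array was assumed to vary like the others. Counts ranged over 7 to 46 higher and 0 to 2 lower at 1 h, 283 to 465 and 245 to 793 at 4 h, 162 to 615 and 116 to 291 in MyD88 KO, and 25 to 177 and 14 to 66 in TRIF KO. Counts moved by over 1.5 times as follows. At 1 h, higher: 12, 46 and 19 without the wild-type, MyD88 KO or TRIF KO arrays, 7 and 14 without the 1 h array of wild type or TRIF KO; lower: 1 without the MyD88 KO arrays, the wild-type 4 h or the MyD88 KO 4 h array, 2 without the MyD88 KO 0 h array. At 4 h, higher: 289 without the wild-type arrays, 283 without the wild-type 4 h array; lower: 267 and 245 without the wild-type or TRIF KO arrays, 352 and 272 without the wild-type 0 h or 4 h array, 367 and 397 without the TRIF KO 0 h or 4 h array. In MyD88 KO, higher and lower: 162 and 116 without the 1 h arrays, 163 and 133 without the 4 h arrays, 241 and 155 without the wild-type 4 h array, 206 and 157 without the MyD88 KO 4 h array. In TRIF KO, higher: 74, 25 and 71 without the 0, 1 or 4 h arrays, 52 without the wild-type 1 h array, 53, 46 and 56 without the TRIF KO 0, 1 or 4 h array; lower: 14 without the 1 h arrays, 66 and 27 without the wild-type 0 h or 1 h array, 25, 22 and 26 without the TRIF KO 0, 1 or 4 h array.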

Other observations

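Probe sets left out because they name several genes or none were also looked at, a check chosen after the results were seen. Of 524 that name several genes and passed the filter, 0 were at least 4-fold higher in wild type at 4 h, and of 886 with no listed gene 1 was, by 2.64 (log2), against 0.63 in MyD88 KO and 1.18 in TRIF KO. Array quality was alike: the Gapdh probe sets at the 3' and 5' ends differed by 0.09 to 0.24 and those of actin by -0.13 to -0.01 on the 9 arrays.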
